A study of Homo sapiens with 59 samples.

How the data were processed

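Polyadenylated RNA of human NK cells was sequenced from stranded libraries, 37 in the blood experiment and 22 in the vector experiment. The authors deposited 1 table of counts per experiment, with 1 column per library. The deposited values are raw counts per Ensembl gene, not normalized. Per the labels, reads were aligned to GRCh38 with HISAT2 2.1.0 and counted with featureCounts, and FastQC and edgeR were also named. The annotation release, the strand setting, the treatment of reads that map to several places and the other tool versions were not stated.

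The tables held 61859 and 62710 gene rows in the blood and vector experiments, after 3 broken lines were left out of the first. Symbols, positions and exon lengths came from GENCODE v29, which gave a symbol for 99.8% and 99.9% of genes and an exon length for 97.1% and 96.4% of those tested. Sex-linked genes (511 in each table) were removed before any test. Genes with enough counts for testing were chosen with filterByExpr (minimum count 10), which left 17542 and 15494 genes holding 99.9% and 99.8% of the counts. Libraries were assigned to groups from their labels, with no library left unassigned, and no 2 libraries of a group were copies of each other.

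Counts were scaled with TMM and tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. All groups of a table were fitted together and no donor term was used. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. There were 14 comparisons, 3 of them interactions. CPM values are scaled by the TMM library size. Common dispersion was 0.106 in the blood and 0.0746 in the vector experiment, and 0.043 and 0.0294 with the donor as a block.

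The 27 gene lists and a pair of cross lists in each direction, 16 key genes, the comparisons, the test and the alternatives were chosen before the data were examined. The cross lists took up to 200 genes per direction from the calls of one experiment and were tested in the other. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, and adjusted over the lists of a comparison. No called list differed in sign between its median, its mean and these tests. Named genes are the key genes, up to 8 higher and 8 lower genes of largest change per comparison, and up to 4 members per list with the smallest p. The largest changes needed an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and the same direction in every donor with both groups, and left out uncharacterised loci, HLA, KIR, immunoglobulin and T cell receptor genes. Only part of the genes so chosen is named. A result for 1 key gene is not reported here.

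Donor numbers pair the libraries within an experiment, and those of the 2 experiments were not linked. After group means were removed, libraries of 1 donor had a median correlation across genes of 0.417 (72 of 80 pairs above 0.1) in the blood experiment and 0.385 (35 of 47) in the vector experiment, against −0.075 and −0.175 for libraries of different donors. Genes are not independent replicates in these correlations. The comparisons were therefore also run with the donor as a block.

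The alternatives were RLE scaling, no filter, a stricter filter (at least 1 CPM), a minimum absolute log2 fold change of 1, DESeq2 1.42.0, only the libraries compared, each library left out in turn, the donor as a block, complete pairs with the block, and the donor as a random effect in limma-voom. After the data were seen, an offset for gene length, that offset with the block, and a fit without 4 day 10 NKAR libraries were added, as were lists of basophil, mast cell, red cell and ribosomal protein genes. Other splits of the libraries were drawn for each comparison, 100 where more than 100 exist.

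The steps were tested on simulated data with 200 changed genes and a further planted list of genes raised 2-fold in each comparison of 2 groups. edgeR made 2.44% to 7.23% false calls and DESeq2 10.8% to 19.5%, with no wrong sign. edgeR recovered 27.9% to 58.1% of genes changed 2-fold and 68.3% to 88.2% of those changed 4-fold. A planted list was found in every comparison of 2 groups.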

Results

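Messenger RNA was sequenced from human natural killer (NK) cells, lymphocytes that kill infected and tumour cells, in 59 libraries from 2 experiments. The blood experiment held 37 libraries in 6 groups from 7 donors. Its NK cells were cultured for 4 or 10 days on plates coated either with agonists of the activating receptors NKp46 and NKG2D (an anti-NKp46 antibody with MICA/B, called NKAR here) or with an isotype control. At day 10 the cytokine IL-15, a survival and growth signal for NK cells, had been given throughout (continuous) or lowered for 2 days in between (gapped). There were 7 NKAR and 6 isotype libraries at day 4, 5 NKAR and 7 isotype libraries at day 10 with continuous IL-15, and 5 NKAR and 7 isotype libraries at day 10 with gapped IL-15. The vector experiment held 22 libraries in 6 groups from 5 donors. Its NK cells were first expanded on K562 leukaemia feeder cells and then transduced with an adeno-associated virus (AAV) carrying either the fluorescent protein mNeonGreen alone (mNG) or KLF2 together with it (KLF2). Each vector had 5 libraries before plating (day 0) and 3 each after 4 days on isotype or NKAR plates.

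The total count per library ranged from 19.1 to 29.7 M (M, 1e6 counts) in the blood experiment (median 24.4 M) and from 12.4 to 19.2 M in the vector experiment (median 16.2 M). Group means ranged from 22.5 M ± 2.17 (SD, n = 7; day 10 isotype with continuous IL-15) to 26.3 M ± 2.84 (SD, n = 7; day 10 isotype with gapped IL-15) in the first experiment. They ranged from 15.2 M ± 1.72 (SD, n = 5; day 0 KLF2) to 17.5 M ± 2.44 (SD, n = 3; day 4 mNG on NKAR plates) in the second. Mitochondrial transcripts made up 3.98% to 10.8% of counts in blood libraries and 6.67% to 13.5% in vector libraries. Expression is given below in counts per 1e6 counts (CPM) as the group mean ± SD over the libraries of the group, and differences as log2 fold changes with adjusted p-values from edgeR. A gene is said to have risen, fallen or been called when its adjusted p was under 0.05. Positions are on GRCh38.

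**Figure D1:**
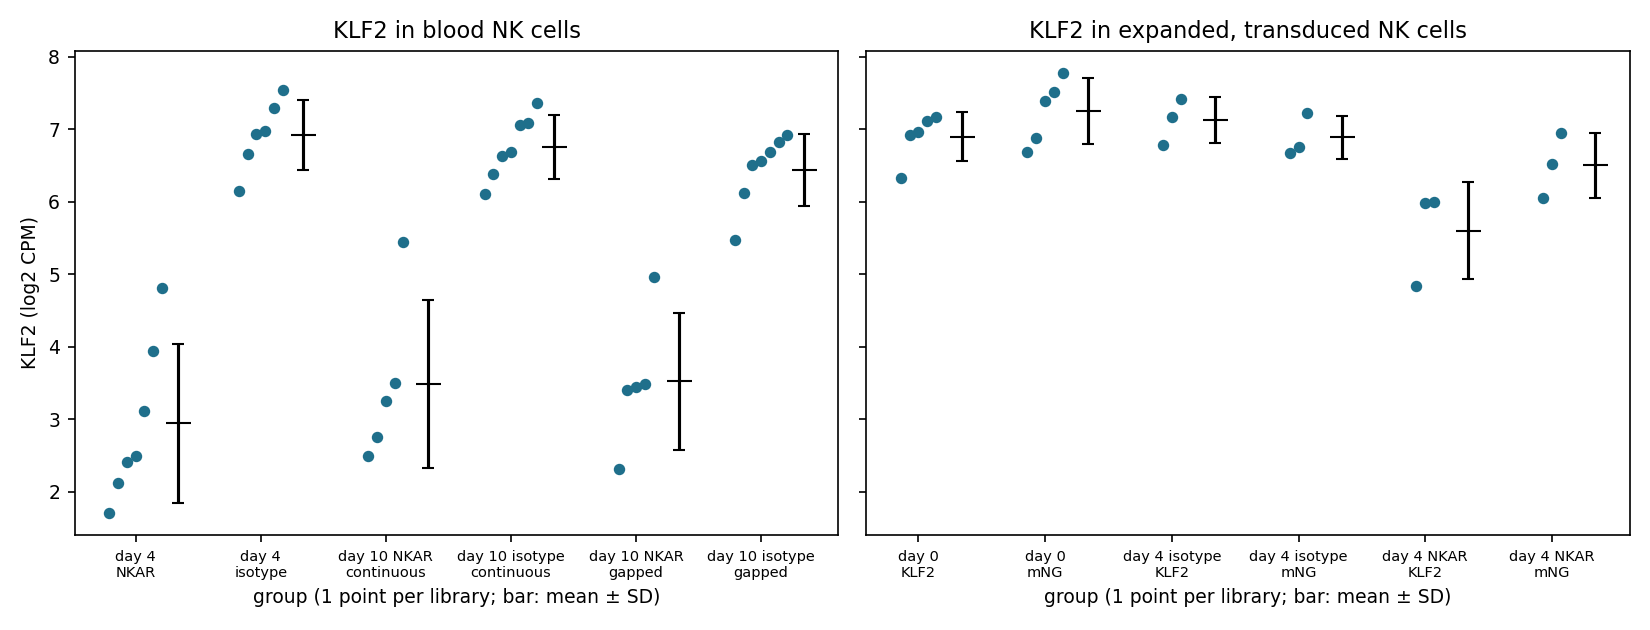
KLF2 in log2 CPM for each library (points) with the group mean and SD (bars), in the blood experiment on the left and the vector experiment on the right. Day 4 NKAR libraries averaged 10.0 CPM against 126.7 CPM in day 4 isotype libraries, and libraries labelled KLF2 did not lie above mNG libraries by a called difference at any time.

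The first comparison asked how 4 days of NKAR stimulation changed blood NK cells. KLF2, a transcription factor that maintains the expression of egress receptors, averaged 10.0 ± 8.92 CPM in 7 NKAR libraries and 126.7 ± 40.2 CPM in 6 isotype libraries (log2 fold change −3.66, adjusted p = 2.57e-07, lower in 6 of 6 donors with both groups). S1PR1, the receptor that guides lymphocytes out of tissue along sphingosine-1-phosphate, averaged 11.4 ± 6.54 against 122.4 ± 26.2 CPM (−3.43, adjusted p = 2.36e-08, lower in 6 of 6). ITGA1, the collagen-binding integrin CD49a of tissue-resident NK cells, averaged 30.9 ± 11.7 against 1.01 ± 0.548 CPM (4.92, adjusted p = 8.73e-13, higher in 6 of 6). KLF2 (ENSG00000127528) is a protein-coding gene on the plus strand of chromosome 19 from 16324817 to 16327874, S1PR1 (ENSG00000170989) is on chromosome 1 from 101236865 to 101243713, and ITGA1 (ENSG00000213949) is on chromosome 5 from 52787896 to 52959210.

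Other key genes moved less or in mixed directions at day 4. The pore-forming protein PRF1 (1603 ± 217 against 2799 ± 521 CPM, −0.80, adjusted p = 2.13e-05) and the transcription factor TBX21 (−0.89, adjusted p = 8.58e-07) fell, lower in 6 of 6 donors. ITGAE, the integrin CD103, rose (0.82, adjusted p = 5.42e-06, 6 of 6). So did the transcription factors TCF7 (1.02, adjusted p = 0.000311, 6 of 6) and EOMES (0.61, adjusted p = 0.00218, 6 of 6). The cytokine gene IFNG rose as well (38.7 ± 22.2 against 4.22 ± 1.68 CPM, 3.20, adjusted p = 1.41e-05, 6 of 6). Genes of the stimulated receptors fell, with calls a single library could end: KLRK1 for NKG2D (−1.05, adjusted p = 0.0329, lower in 6 of 6) and NCR1 for NKp46 at low counts (0.315 against 0.937 CPM, −1.55, adjusted p = 0.0339, lower in 5 of 6). The protease gene GZMB (−0.08, adjusted p = 0.782), the early activation marker CD69 (0.35, adjusted p = 0.271) and the chemokine receptor CXCR6 (−0.16, adjusted p = 0.778) did not pass the test. S1PR5, another sphingosine-1-phosphate receptor, stood at −0.68 (adjusted p = 0.116, and 0.00245 with the donor as a block, lower in 5 of 6).

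Among the largest changes, the chemokine gene CCL1 averaged 167.6 ± 160 against 0.437 ± 0.268 CPM (log2 fold change 8.59, adjusted p = 1.25e-08, higher in 6 of 6). The prostacyclin receptor PTGIR averaged 120.6 ± 51.5 against 0.535 ± 0.458 CPM (7.80, adjusted p = 8.2e-10, 6 of 6). SNAP25, a membrane fusion protein, averaged 9.33 ± 4.99 against 0.045 ± 0.0456 CPM (7.56, adjusted p = 2.25e-09, 6 of 6). In the other direction, the interleukin-8 receptor CXCR1 averaged 0.865 ± 0.61 against 41.3 ± 14.1 CPM (−5.57, adjusted p = 8.38e-09, lower in 6 of 6). The prostaglandin D2 synthase PTGDS averaged 0.709 ± 1.03 against 33.4 ± 21.3 CPM (−5.53, adjusted p = 3.12e-07, 6 of 6). LGR6, a receptor of R-spondins, averaged 3.64 ± 4.89 against 74.0 ± 44.6 CPM (−4.34, adjusted p = 2.31e-05, 6 of 6).

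The gene lists were fixed in advance. Where a single count is given for a list, it was the same adjusted over the list alone. In the tissue residency list 6 of 16 measured genes rose and 3 fell (7 and 4 adjusted over the list alone), among them CRTAM (565.5 ± 213 against 44.5 ± 17.1 CPM, 3.67), RGS1 (2.80) and DUSP4 (4.94). The list was called higher (adjusted p = 0.0117), but not at adjusted p = 0.253 with an estimated correlation. Of 13 egress and circulation genes 8 fell and 1 rose (adjusted p = 1.23e-05, adjusted p = 0.093 with an estimated correlation). Of 12 genes that mark mature CD56dim NK cells 10 fell, including the adhesion receptor ADGRG1 (100.8 ± 27.7 against 617.0 ± 160 CPM, −2.61) and FGFBP2 (−3.12). The list had adjusted p = 1.31e-07, and adjusted p = 0.093 with an estimated correlation. Among 17 cytotoxic effectors 8 fell and 2 rose, with the granzymes GZMA (−1.39) and GZMH (−2.38) among those that fell (adjusted p = 0.0114, adjusted p = 0.365 with an estimated correlation). Among 17 activating receptors and adaptors 12 fell and 1 rose, including the kinase ZAP70 (−1.33; adjusted p = 0.00115, adjusted p = 0.0958 with an estimated correlation). Of 11 chemokine receptors 7 fell (7 fell and 1 rose adjusted over the list alone), including CXCR2 (−3.42; adjusted p = 0.000382, adjusted p = 0.0543 with an estimated correlation).

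Activation lists were tested next. Among 19 activation-induced transcription factors 11 rose and 2 fell (11 and 3 adjusted over the list alone), with IRF4 (196.9 ± 37.1 against 20.5 ± 6.86 CPM, 3.27), EGR2 (2.77) and NR4A3 (3.03) as examples. The list had adjusted p = 0.000351, and adjusted p = 0.0941 with an estimated correlation. Among 14 genes of the costimulatory TNF family 9 rose and 2 fell, including TNFRSF9, which encodes 4-1BB (905.3 ± 297 against 40.6 ± 16.4 CPM, 4.48, adjusted p = 8.73e-13), TNFSF4 (4.45) and TNFRSF4 (3.36). That list had adjusted p = 1.49e-05, and adjusted p = 0.0543 with an estimated correlation. Of 12 cytokine and chemokine genes 6 rose and 1 fell (8 and 1 adjusted over the list alone), including CCL22 (7.32) and CSF2 (3.77). The list had adjusted p = 0.00329, and adjusted p = 0.0941 with an estimated correlation. Of 14 inhibitory receptors 6 rose and 2 fell, including CTLA4 (46.9 ± 26.2 against 1.08 ± 0.678 CPM, 5.42) and the ectonucleotidase ENTPD1 (549.8 ± 165 against 81.4 ± 63 CPM, 2.76). The inhibitory list as a whole was not called (adjusted p = 0.177).

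Metabolic and stress lists followed. In oxidative phosphorylation 14 of 18 genes rose (adjusted p = 9.48e-07, adjusted p = 0.205 with an estimated correlation). The mitochondrial share of counts was 7.93% ± 1.53 in day 4 NKAR and 5.70% ± 0.345 in day 4 isotype libraries. In glycolysis 10 of 16 rose and 2 fell, including GAPDH (1.02) and the hexokinase HK2 (2.54; adjusted p = 0.0177, adjusted p = 0.603 with an estimated correlation). In sterol and lipid synthesis 8 of 18 rose and 2 fell (adjusted p = 0.00558, adjusted p = 0.414 with an estimated correlation). Among heat shock genes 8 of 9 rose and 1 fell, including the chaperonin HSPD1 (1.23; adjusted p = 0.000174, adjusted p = 0.205 with an estimated correlation). Of 23 cell cycle genes 5 rose (1 adjusted over the list alone; adjusted p = 0.0368, adjusted p = 0.712 with an estimated correlation). Of 18 interferon response genes 6 fell (adjusted p = 0.0208, adjusted p = 0.365 with an estimated correlation). The lists of NK lineage transcription factors (5 higher and 5 lower of 17, adjusted p = 0.514) and of the IL-15 and STAT5 response (4 higher and 2 lower of 17, 3 and 2 adjusted over the list alone; adjusted p = 0.241) were not called. The IL-2 receptor chain gene IL2RA in the latter rose (3.00). The TGF-beta response (2 higher and 7 lower of 12, 3 and 8 adjusted over the list alone), integrated and ER stress response (2 higher and 3 lower of 14, 1 and 1 adjusted over the list alone) and p53 target lists (2 higher and 1 lower of 15) were not called either. Among lists of other cells, 1 T cell gene was higher and 3 lower of 12. Of B cell genes 1 of 8 and of platelet and red cell genes 2 of 4 were higher, and 2 of 8 innate lymphoid type 2 and 3 genes were lower. No monocyte, dendritic or K562 gene was called, and no such list was called.

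In all, edgeR called 7024 of 17542 genes at day 4, 3572 higher and 3452 lower. NCR1 lost its call without replicates 1, 4, 10 or 13 of the NKAR group or replicates 10 or 11 of the isotype group (adjusted p up to 0.17). KLRK1 lost its call without replicates 1, 3, 4 or 11 of the NKAR group or replicates 10, 13 or 14 of the isotype group (adjusted p up to 0.0813) or with no filter on low counts (adjusted p = 0.0651). S1PR5 was called without replicate 13 of the NKAR group (−1.19, adjusted p = 0.0019).

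**Figure D2:**
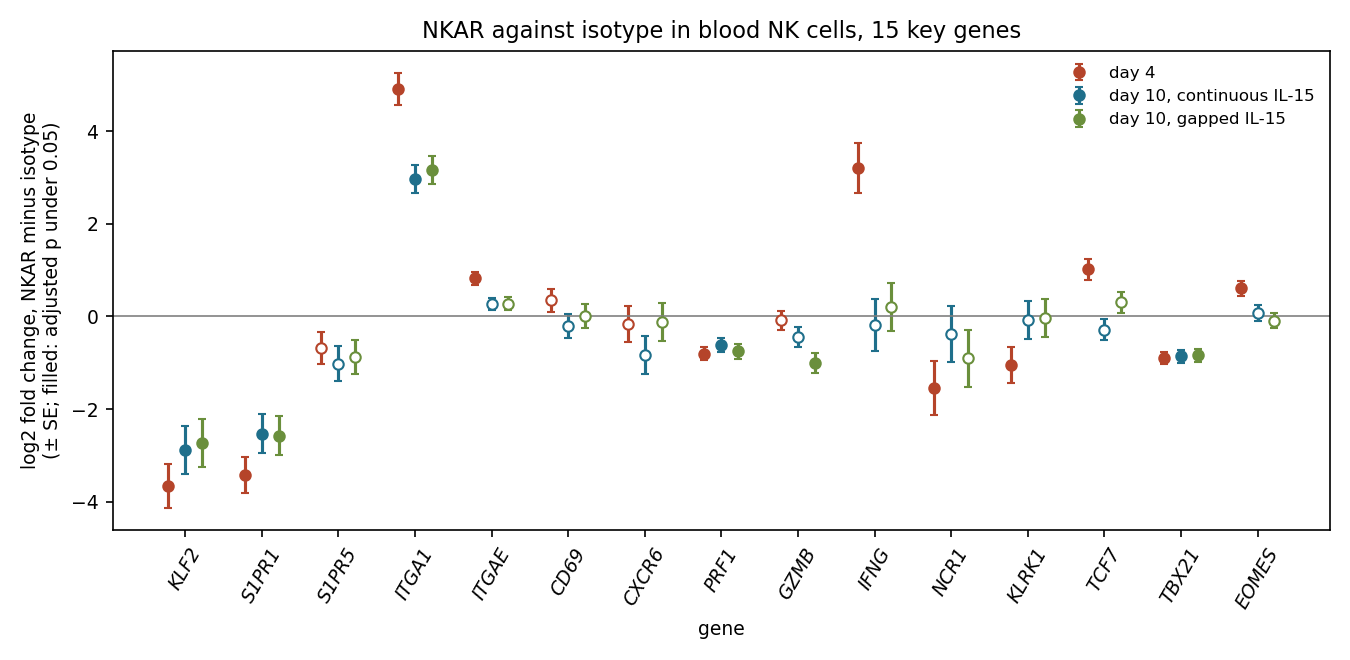
Log2 fold change of 15 key genes, NKAR minus isotype, in blood NK cells at day 4 and at day 10 under both IL-15 regimes; bars are SE and filled points have an adjusted p under 0.05. KLF2 lies at −3.66, −2.88 and −2.73, and ITGA1 at 4.92, 2.97 and 3.16.

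The next comparison asked which NKAR differences were present at day 10 with continuous IL-15. KLF2 averaged 15.3 ± 15.9 CPM in 5 NKAR libraries and 112.2 ± 33.5 CPM in 7 isotype libraries (−2.88, adjusted p = 0.000296, lower in 5 of 5 donors with both). S1PR1 (24 ± 15.9 against 139.0 ± 49.4 CPM, −2.53, adjusted p = 0.000104), PRF1 (−0.61, adjusted p = 0.00726) and TBX21 (−0.86, adjusted p = 4.91e-05) were lower in 5 of 5. ITGA1 was higher in 5 of 5 (23.4 ± 5.13 against 2.98 ± 1.26 CPM, 2.97, adjusted p = 3.88e-08). The largest falls included KCNK17, a potassium channel (adjusted p = 1.18e-05), and IL1RL1, the interleukin-33 receptor (−3.58, adjusted p = 3.38e-05), each lower in 5 of 5. The adhesion molecule VCAM1 rose (54.0 ± 43.5 against 0.692 ± 0.448 CPM, 6.26, adjusted p = 4.74e-07, 5 of 5). IFNG (−0.19, adjusted p = 0.917) and TCF7 (−0.28, adjusted p = 0.576) did not pass the test at this time. S1PR5 stood at −1.02 (adjusted p = 0.0979, lower in 5 of 5), with adjusted p = 0.000942 with the donor as a block.

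By function, 7 of 13 egress and circulation genes fell (10 adjusted over the list alone; adjusted p = 9.91e-11), including the fractalkine receptor CX3CR1 (70.6 ± 73.2 against 365.2 ± 149 CPM, −2.37) and the integrin ITGAM. This list was also called with an estimated correlation (adjusted p = 0.0108). Of 11 chemokine receptors 8 fell, including CCR2 (−2.97). The list was called (adjusted p = 1.9e-10), also with an estimated correlation (adjusted p = 0.000289). Of 14 inhibitory receptors 6 rose and 2 fell (7 and 2 adjusted over the list alone), including LAYN (49.0 ± 20.7 against 4.08 ± 2.13 CPM, 3.58), CTLA4 (4.14), ENTPD1 (2.55) and HAVCR2, which encodes TIM-3 (1.17). That list had adjusted p = 0.000101 (adjusted p = 0.0545 with an estimated correlation). Tissue residency genes rose (5 of 16, 7 adjusted over the list alone; adjusted p = 0.000264, adjusted p = 0.111 with an estimated correlation). CD56dim maturity genes fell (4 of 12, 6 adjusted over the list alone; adjusted p = 1.21e-05, adjusted p = 0.131 with an estimated correlation). Cytotoxic effectors also fell (5 of 17, 6 adjusted over the list alone; adjusted p = 1.73e-05, adjusted p = 0.111 with an estimated correlation). Members of these 2 lists that fell include FGFBP2 (−1.93) and the granzyme GZMK (27.2 ± 9.2 against 232.5 ± 82.6 CPM, −3.09). Costimulatory genes rose (4 higher and 2 lower of 14, 7 and 2 adjusted over the list alone; adjusted p = 0.00378, adjusted p = 0.176 with an estimated correlation), with TNFRSF9 at 96.8 ± 35.2 against 14.7 ± 5.35 CPM (2.72). Activation-induced transcription factors rose (5 higher and 3 lower of 19, 6 and 4 adjusted over the list alone; adjusted p = 0.00752, adjusted p = 0.219 with an estimated correlation). The cell cycle and heat shock lists had no called member, and the cytokine list (3 higher of 12, 3 higher and 1 lower adjusted over the list alone; adjusted p = 0.212) was not called.

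Transcripts of other blood cells moved with this comparison. The haemoglobin genes HBB (49.5 ± 66.6 against 0.207 ± 0.391 CPM, 7.73, adjusted p = 0.000783) and HBD were higher in 5 of 5 donors (HBD 26.3 ± 34.9 against 0.125 ± 0.214 CPM, 7.56, adjusted p = 0.00115). So were the scavenger receptor CD36 (5.24 ± 6.88 CPM, adjusted p = 0.00374) and the lysozyme gene LYZ (15.2 ± 24.1 against 0.33 ± 0.492 CPM, 5.51, adjusted p = 0.00114). Of 8 monocyte and dendritic genes 5 rose (6 adjusted over the list alone; adjusted p = 0.000101, adjusted p = 0.104 with an estimated correlation), including FCER1A (3.52), a chain of the IgE receptor. Of 4 platelet and red cell genes 3 rose (4 adjusted over the list alone; adjusted p = 0.0219, adjusted p = 0.324 with an estimated correlation). Of 8 B cell genes 4 rose (adjusted p = 0.00329, adjusted p = 0.131 with an estimated correlation). The K562 list was not called, but its members TAL1 (5.74) and GATA1 (5.65), transcription factors of red cell and mast cell precursors, were higher. The T cell list was not called (2 higher of 12). The SD over the 5 NKAR libraries exceeded the mean for HBB, HBD, CD36, LYZ, TAL1 and GATA1.

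At day 10 with continuous IL-15 edgeR called 1410 genes, 762 higher and 648 lower. After the 4 day 10 NKAR libraries with the most basophil, mast and red cell transcripts (2 per IL-15 regime) were left out, 725 genes were called, 700 of them among the 1410 in the same direction. This choice was made after the data were seen and itself lowers such transcripts. In that fit FGFBP2 stood at −1.64 and was not called (adjusted p = 0.0902). HBB (2.45, adjusted p = 0.428) and HBD (2.61, adjusted p = 0.395) were no longer called. The same held for CD36 (3.40, adjusted p = 0.259), LYZ (3.44, adjusted p = 0.0677), TAL1 (2.85, adjusted p = 0.11), GATA1 (1.32, adjusted p = 0.697) and FCER1A (2.13, adjusted p = 0.262). In that fit 5 of 13 egress genes, 6 of 11 chemokine receptors, 3 of 17 cytotoxic effectors and 1 of 12 CD56dim maturity genes were called lower. No B cell gene of 8 and no monocyte and dendritic gene of 6 was called. PRF1 was not called when only the 12 compared libraries were fitted (adjusted p = 0.058). S1PR5 was called with DESeq2 (adjusted p = 0.0357) and without replicate 13 of the NKAR group (−1.49, adjusted p = 0.0103).

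**Figure D3:**
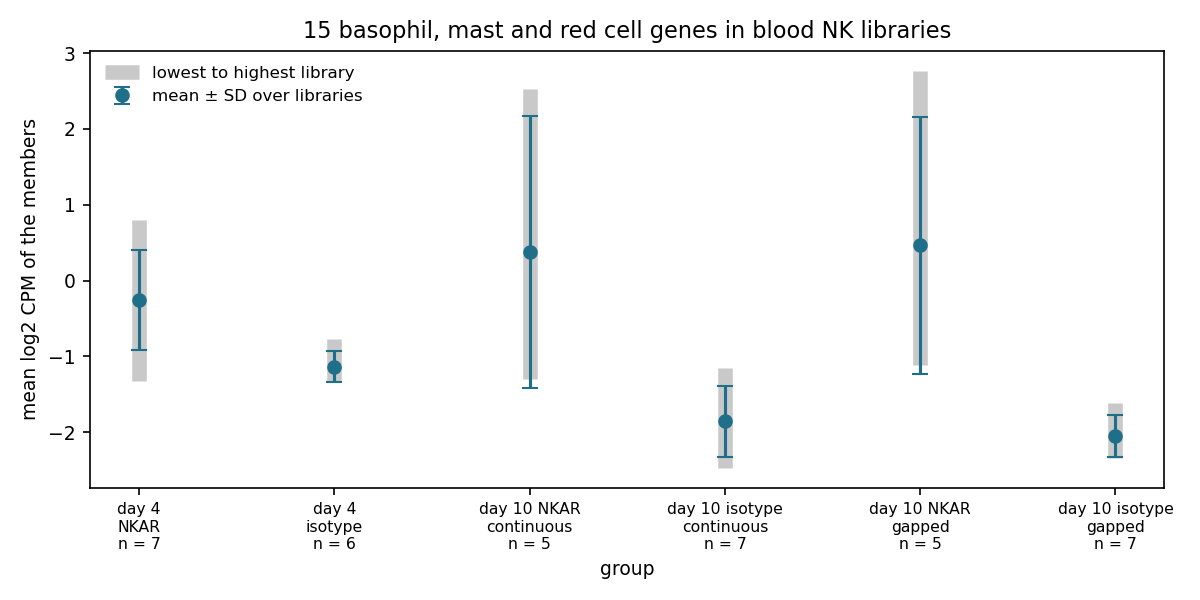
Mean log2 CPM of 15 basophil, mast and red cell genes in the blood groups: points and bars are the mean ± SD over libraries, grey bands run from the lowest to the highest library. Day 10 NKAR libraries ranged from −1.30 to 2.53 (continuous IL-15) and from −1.12 to 2.77 (gapped IL-15), against means of −1.86 and −2.05 in their isotype groups.

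The same question was asked at day 10 with gapped IL-15. KLF2 (13.7 ± 10 CPM in 5 NKAR libraries against 90.6 ± 26.3 CPM in 7 isotype libraries, −2.73, adjusted p = 0.000447) and S1PR1 (19.8 ± 10.7 against 117.7 ± 49.1 CPM, −2.58, adjusted p = 7.42e-05) were lower in 5 of 5 donors. ITGA1 was higher in 5 of 5 (19.2 ± 2 against 2.12 ± 1.03 CPM, 3.16, adjusted p = 1.27e-08). GZMB, the main granzyme of killing, fell here (204.7 ± 16.2 against 410.2 ± 114 CPM, adjusted p = 0.00234, lower in 5 of 5). PRF1 (−0.76, adjusted p = 0.000794, 5 of 5) and TBX21 (−0.84, adjusted p = 5.82e-05, 5 of 5) fell as well. CXCR1 (−3.65, adjusted p = 0.000143), IL1RL1 (−3.35, adjusted p = 3.62e-05) and RAP1GAP2, a regulator of the GTPase RAP1 (9.05 ± 5.55 against 78.2 ± 29.2 CPM, −3.11, adjusted p = 2.52e-06), were among the largest falls, each in 5 of 5.

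Cytotoxic effectors fell (6 of 17, 11 adjusted over the list alone; adjusted p = 3.57e-10, and adjusted p = 0.0191 with an estimated correlation), including GZMK (−2.73), GZMA (294.9 ± 44.2 against 738.8 ± 117 CPM) and GZMH (−2.20). Egress genes fell (6 of 13, 10 adjusted over the list alone; adjusted p = 7.73e-09, and adjusted p = 0.0191 with an estimated correlation). Chemokine receptors fell (8 of 11, 8 lower and 1 higher adjusted over the list alone; adjusted p = 3.79e-08, and adjusted p = 0.00293 with an estimated correlation). Tissue residency genes rose (5 of 16, 6 adjusted over the list alone; adjusted p = 1.84e-05, and adjusted p = 0.0488 with an estimated correlation). Without the 4 NKAR libraries named above 3 of the 16 were called, and the list had adjusted p = 0.0537 with an estimated correlation. Inhibitory receptors rose (7 higher and 2 lower of 14; adjusted p = 0.000248, and adjusted p = 0.0488 with an estimated correlation), with CTLA4 at 13.1 ± 8.85 against 0.376 ± 0.255 CPM (5.08). CD56dim maturity genes fell (4 of 12, 7 adjusted over the list alone; adjusted p = 4.07e-07, adjusted p = 0.0807 with an estimated correlation). Activation-induced transcription factors rose (5 higher and 2 lower of 19, 7 and 3 adjusted over the list alone; adjusted p = 0.000747, adjusted p = 0.0994 with an estimated correlation), with EGR3 at 63.9 ± 12 against 14.4 ± 4.64 CPM (2.15). Costimulatory genes rose (5 higher and 2 lower of 14, 8 and 2 adjusted over the list alone; adjusted p = 0.000415, adjusted p = 0.0893 with an estimated correlation). Cytokines rose (3 higher and 1 lower of 12, 4 and 1 adjusted over the list alone; adjusted p = 0.0258, adjusted p = 0.192 with an estimated correlation). Monocyte and dendritic genes rose (6 of 8; adjusted p = 1.24e-05, and adjusted p = 0.0488 with an estimated correlation). Platelet and red cell genes rose (3 of 4, 4 adjusted over the list alone; adjusted p = 0.0258, adjusted p = 0.308 with an estimated correlation). B cell genes rose (2 of 8, 3 adjusted over the list alone; adjusted p = 0.0139, adjusted p = 0.192 with an estimated correlation). RNASE2, an eosinophil granule ribonuclease, stood at 7.07 ± 9.99 against 0.0777 ± 0.0932 CPM (6.49, adjusted p = 0.000199) and HBD at 20.3 ± 28.8 against 0.106 ± 0.251 CPM (7.57, adjusted p = 0.00121), each higher in 5 of 5.

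With gapped IL-15 edgeR called 1414 genes, 810 higher and 604 lower, and 2318 (1229 higher, 1089 lower) with the donor as a block. Without the same 4 NKAR libraries 781 were called, 728 of them among the 1414 in the same direction, and HBD (4.02, adjusted p = 0.0965) was not. Of the genes called at day 10, 526 rose and 410 fell under both regimes, against 35.2 and 22.3 expected if the calls were unrelated, although the donors of the groups overlap.

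**Figure D4:**
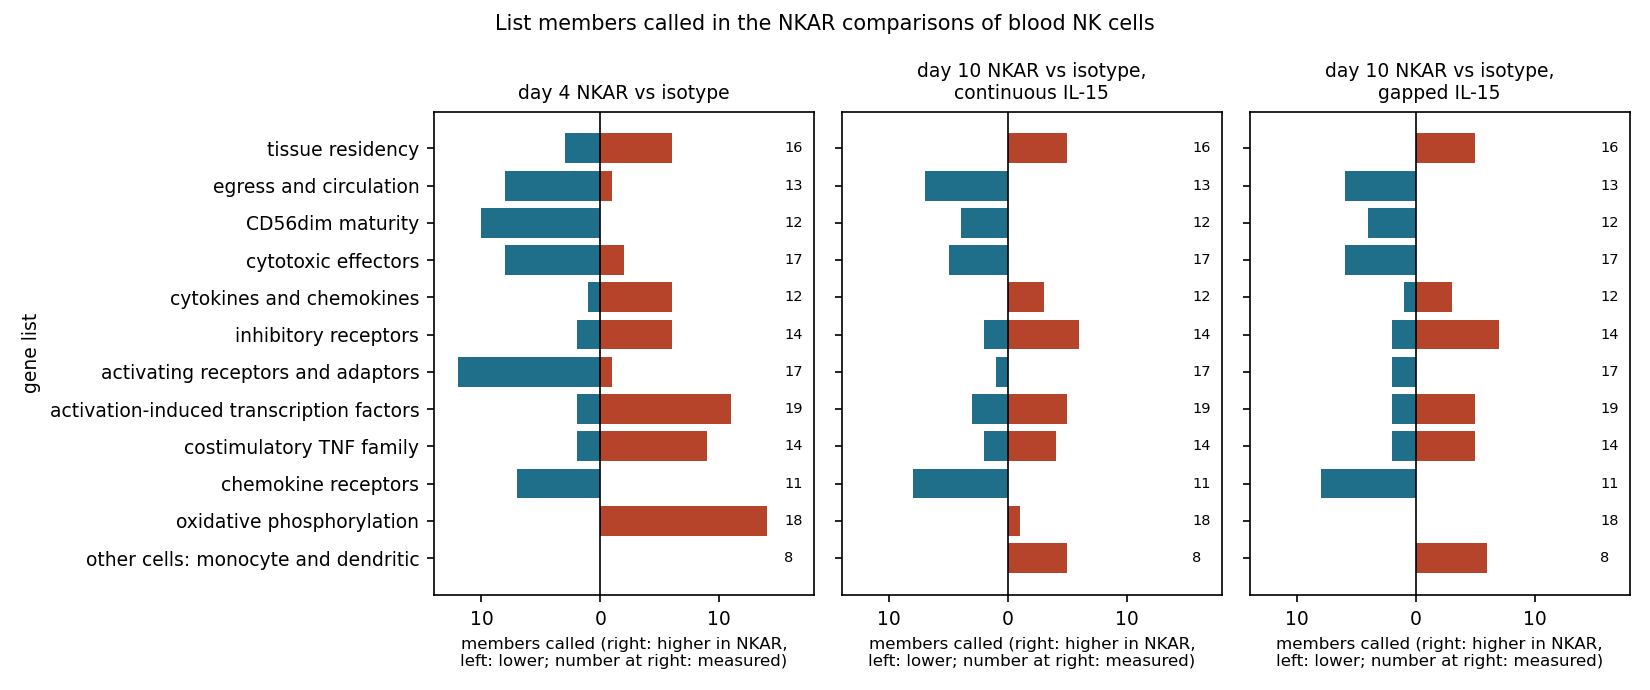
Number of genes of 12 lists called higher (right) or lower (left) in NKAR than in isotype libraries, in the 3 NKAR comparisons of blood NK cells; the figure at the right edge is the number measured. Egress genes called lower numbered 8, 7 and 6 of 13, and inhibitory receptors called higher numbered 6, 6 and 7 of 14.

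Whether the NKAR effect differed between the days was tested as an interaction, day 10 with continuous IL-15 minus day 4. The effect was smaller at day 10 for ITGA1 (−1.95, adjusted p = 0.00531) and TCF7 (−1.30, adjusted p = 0.00966), and lower at day 10 for IFNG (−3.39, adjusted p = 0.00632). CSF2, which encodes the cytokine GM-CSF (−4.15, adjusted p = 9.07e-05), TRIB1 (−3.87, adjusted p = 0.00021) and the G protein regulator RGS16 (−3.53, adjusted p = 0.0103) were among the largest differences. KLF2 did not pass the test (0.78, adjusted p = 0.5). The NKAR effect was lower at day 10 for cytokine genes (1 higher and 4 lower of 12; adjusted p = 0.00193, adjusted p = 0.166 with an estimated correlation). The same held for costimulatory genes (3 lower of 14, 7 adjusted over the list alone; adjusted p = 4.88e-05, adjusted p = 0.166 with an estimated correlation). It held for oxidative phosphorylation (6 lower of 18, 12 adjusted over the list alone; adjusted p = 6.28e-07, adjusted p = 0.258 with an estimated correlation) and heat shock genes (4 lower of 9, 6 adjusted over the list alone; adjusted p = 2.54e-05, adjusted p = 0.241 with an estimated correlation). CD56dim maturity genes (4 higher of 12; adjusted p = 0.000521, adjusted p = 0.3 with an estimated correlation) and activating receptors (3 higher of 17, 5 higher and 1 lower adjusted over the list alone; adjusted p = 0.00281, adjusted p = 0.241 with an estimated correlation) had a higher one. The mast cell and basophil genes GATA2 (3.55, adjusted p = 0.0145) and HDC (3.14, adjusted p = 0.0142) also had a higher effect at day 10. In all 1388 genes were called (634 higher, 754 lower), and 2604 with the donor as a block. The count was 879 without replicate 14 of the day 10 NKAR group with continuous IL-15. It was 760 without the 4 libraries rich in other blood cell transcripts, and GATA2 (2.32, adjusted p = 0.116) and HDC (1.91, adjusted p = 0.141) were no longer called.

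The effect of the IL-15 gap was first tested without stimulation. Isotype libraries with gapped IL-15 (7) were compared with 7 with continuous IL-15. MKI67, the marker Ki-67 of cycling cells, averaged 750.9 ± 226 against 241.5 ± 148 CPM (1.64, adjusted p = 0.00403, higher in 7 of 7 donors). Of 23 cell cycle genes 21 rose (23 adjusted over the list alone; adjusted p = 5.09e-30, adjusted p = 0.192 with an estimated correlation). Examples are the helicase subunit MCM4 (122.2 ± 68.5 against 33.0 ± 18.5 CPM, 1.89), the mitotic kinases AURKA (1.76) and BUB1 (1.63), and the replication factors GINS2 (2.69) and CDC6 (2.29). Sterol and lipid synthesis rose (9 of 18, 10 adjusted over the list alone; adjusted p = 4.87e-07, adjusted p = 0.49 with an estimated correlation). Its members include the desaturase SCD (34.6 ± 19.9 against 11.4 ± 6.17 CPM, adjusted p = 0.00404). So did oxidative phosphorylation (9 of 18, 12 adjusted over the list alone; adjusted p = 1.39e-06, adjusted p = 0.529 with an estimated correlation). Glycolysis rose (3 of 16, 7 adjusted over the list alone; adjusted p = 0.00463, adjusted p = 0.901 with an estimated correlation), as did heat shock genes (3 of 9, 5 adjusted over the list alone; adjusted p = 0.0161, adjusted p = 0.901 with an estimated correlation). COL24A1, a collagen (−2.82, adjusted p = 0.00391), and BAIAP3, a protein of vesicle release (15.3 ± 6.52 against 51.0 ± 23.7 CPM, adjusted p = 0.00287), were lower in 7 of 7. KLF2 did not pass the test (−0.31, adjusted p = 0.745), and GZMB stood at 0.55 (adjusted p = 0.0801, higher in 6 of 7).

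For this comparison edgeR called 1384 genes, 1093 higher and 291 lower, and 2657 (1751 higher, 906 lower) with the donor as a block, where GZMB was called (adjusted p = 0.00964). With continuous replicates 10, 13 or 14 left out the count was 898, 768 or 912, and with gapped replicates 1 or 3 left out it was 764 or 560. GZMB was called without replicate 11 of the continuous group (0.74, adjusted p = 0.00996) or replicate 10 of the gapped group (0.63, adjusted p = 0.0393).

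Under NKAR stimulation the gap gave no called gene with edgeR over 10 libraries, with 1105 genes at an unadjusted p under 0.05. DESeq2 called 7, limma-voom with the donor as a random effect 264, and edgeR 400 (376 higher, 24 lower) with the donor as a block. The cell cycle list was called higher with gapped IL-15 (no member called over all genes, 21 of 23 adjusted over the list alone; adjusted p = 3e-29, adjusted p = 0.207 with an estimated correlation). Its members PCNA (185.5 ± 105 against 77.3 ± 40.7 CPM, 1.26, adjusted p = 0.325, and 0.00148 with the block) and RRM2 were higher in 3 of 3 donors with both groups (RRM2 1.70, adjusted p = 0.358, and 0.000945 with the block). So were E2F1 (1.28, adjusted p = 0.325, and 0.00148 with the block) and CDK1 (45.0 ± 14.4 against 18.3 ± 11.8 CPM, adjusted p = 0.367, and 0.00437 with the block). Without replicate 1 of the continuous NKAR group 123 genes were called (122 higher, 1 lower), with PCNA (1.62, adjusted p = 0.0362), RRM2 (2.35, adjusted p = 0.034) and E2F1 (1.84, adjusted p = 0.0288) among them. The difference between the gap effects with and without NKAR gave no called gene with edgeR, with or without the donor block, and none with DESeq2, with 323 genes at an unadjusted p under 0.05. Its cell cycle (adjusted p = 0.000955), sterol (adjusted p = 2.27e-06), oxidative phosphorylation (adjusted p = 0.00157), glycolysis (adjusted p = 0.00457) and cytotoxic lists (adjusted p = 0.0147) were called lower, and each had adjusted p = 0.979 with an estimated correlation.

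Time in culture was compared without stimulation. Between day 4 and day 10 with continuous IL-15, 23 of 23 cell cycle genes fell (adjusted p = 4.16e-24, adjusted p = 0.396 with an estimated correlation). Among them were MCM4 (33.0 ± 18.5 in 7 libraries against 256.3 ± 82.4 CPM in 6, −2.96), the replication clamp PCNA (88.9 ± 49.3 against 445.4 ± 99.6 CPM) and MCM6 (−2.51). GZMB fell (279.6 ± 105 against 840.7 ± 136 CPM, −1.59, adjusted p = 7.1e-07, lower in 6 of 6 donors). TCF7 (791.3 ± 229 against 282.5 ± 73.5 CPM, 1.49, adjusted p = 5.6e-06) and LEF1 (1.75, adjusted p = 1.63e-07), transcription factors of less differentiated lymphocytes, rose in 6 of 6. So did the IL-7 receptor IL7R (2.05, adjusted p = 0.00387), CXCR6 (1.87, adjusted p = 0.000558) and ITGA1 (1.55, adjusted p = 0.00034). CCR2 (1.85, adjusted p = 0.000832), GZMK (1.97, adjusted p = 2.19e-05) and the stem cell factor receptor KIT (355.8 ± 67.5 against 153.9 ± 48.6 CPM, 1.21, adjusted p = 0.000908) rose in 6 of 6 too. The largest changes included COL24A1 (4.12, adjusted p = 2.76e-05) and the growth factor gene BMP2 (2.56, adjusted p = 4.51e-07), higher in 6 of 6. UHRF1, which maintains DNA methylation (19.0 ± 14.4 against 208.3 ± 92 CPM, −3.46, adjusted p = 1.25e-05), and RHBDL3 (−5.37, adjusted p = 7.34e-07) were lower in 6 of 6. Sterol synthesis (8 of 18; adjusted p = 0.00174) and oxidative phosphorylation (10 of 18, 13 adjusted over the list alone; adjusted p = 0.00161) fell, each with adjusted p = 0.506 with an estimated correlation. Interferon response (9 of 18, 11 adjusted over the list alone; adjusted p = 0.00143), heat shock (5 of 9, 6 adjusted over the list alone; adjusted p = 0.00361) and CD56dim maturity genes (4 of 12, 7 adjusted over the list alone; adjusted p = 0.0122) fell. P53 targets rose (6 higher and 1 lower of 15, 7 and 1 adjusted over the list alone; adjusted p = 0.0107). Each of these 4 lists had adjusted p = 0.506 with an estimated correlation. In all 4782 genes were called by edgeR, 2194 higher and 2588 lower. Culture time and harvest day coincide in this comparison by design.

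The vector experiment asked what a KLF2 vector changed. No difference in KLF2 counts between libraries labelled KLF2 and mNG was called. At day 0 KLF2 averaged 121.3 ± 25 CPM in 5 KLF2 libraries and 157.6 ± 48 CPM in 5 mNG libraries (−0.38, 95% interval −0.888 to 0.132, adjusted p = 0.621). On isotype plates it averaged 141.3 ± 30.2 against 119.8 ± 25.6 CPM (0.24, 95% interval −0.42 to 0.896, adjusted p = 0.854). On NKAR plates it averaged 51.5 ± 20.1 against 93.5 ± 28.5 CPM (−0.86, 95% interval −1.52 to −0.193, adjusted p = 0.102, and 0.0472 with the donor as a block). How reads of the vector insert were counted is not stated. KLF2 libraries or cells are so called here by their label alone.

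At day 0 single genes of maturity and killing were higher in libraries labelled KLF2, while PRF1 did not pass the test (adjusted p = 0.285). ADGRG1 (ENSG00000205336, chromosome 16 from 57610652 to 57665580) averaged 108.1 ± 3.2 against 14.8 ± 3.41 CPM (2.87, adjusted p = 2.71e-11, higher in 5 of 5 donors). GZMB averaged 3068 ± 531 against 1386 ± 339 CPM (1.15, adjusted p = 0.00403, 5 of 5). S1PR5 rose (91.2 ± 29.8 against 42.8 ± 17.2 CPM, 1.09, adjusted p = 0.0222, 5 of 5). So did CX3CR1 (465.3 ± 61.9 against 167.1 ± 60.5 CPM, 1.48, adjusted p = 0.00129), FGFBP2 (1.64, adjusted p = 0.000681) and ITGAM (1.07, adjusted p = 0.00212), each in 5 of 5. CXCR1 (adjusted p = 0.0117, 26.6 ± 7.85 against 9.65 ± 3.13 CPM), the receptor tyrosine kinase ERBB2 (1.91, adjusted p = 0.000681) and C1orf162 (adjusted p = 0.000406, 8.56 ± 2.72 against 1.51 ± 0.746 CPM) rose in 5 of 5 as well. The lymph node homing receptor CCR7 (1.07 ± 0.489 against 12 ± 5.58 CPM, −3.47, adjusted p = 0.00129), the transcription factor TOX2 (−1.81, adjusted p = 0.00329) and the ATP-gated channel P2RX5 (−2.75, adjusted p = 0.00306) were lower in 5 of 5. S1PR1 (−0.08, adjusted p = 0.945) did not pass the test.

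Of 12 CD56dim maturity genes 6 rose at day 0 (8 adjusted over the list alone; adjusted p = 1.12e-28, and adjusted p = 0.000896 with an estimated correlation). Egress genes rose (3 higher and 1 lower of 13, 6 and 1 adjusted over the list alone; adjusted p = 1.74e-05, adjusted p = 0.105 with an estimated correlation). Cytotoxic effectors (3 higher of 17; adjusted p = 0.00174, adjusted p = 0.0905 with an estimated correlation) and TGF-beta response genes (2 higher of 11, 3 adjusted over the list alone; adjusted p = 0.0107, adjusted p = 0.123 with an estimated correlation) rose as lists. NK lineage transcription factors were called higher with no member called over all genes (2 of 17 adjusted over the list alone; adjusted p = 0.00174, and adjusted p = 0.0464 with an estimated correlation). Glycolysis was called lower (1 of 16, 4 adjusted over the list alone; adjusted p = 4.95e-07, adjusted p = 0.123 with an estimated correlation). Oxidative phosphorylation was called lower (no member called, 1 of 18 adjusted over the list alone; adjusted p = 1.74e-05, adjusted p = 0.123 with an estimated correlation), as were heat shock genes (no member called, 2 adjusted over the list alone; adjusted p = 0.000129, adjusted p = 0.123 with an estimated correlation). Of 198 genes lower with NKAR in blood at day 4, 24 were higher in KLF2 libraries and none lower (53 and 2 adjusted over the list alone; adjusted p = 3.64e-23, adjusted p = 0.0774 with an estimated correlation). Of 179 genes higher with NKAR in blood, 7 were lower and none higher (20 and 1 adjusted over the list alone; adjusted p = 6.21e-11, and adjusted p = 0.0106 with an estimated correlation). In the reverse direction, of 95 genes higher in day 0 KLF2 libraries 71 fell and 4 rose with NKAR in blood at day 4 (71 and 5 adjusted over the list alone; adjusted p = 8.85e-27, and adjusted p = 0.011 with an estimated correlation). Of 112 lower genes 59 rose and 21 fell (63 and 23 adjusted over the list alone; adjusted p = 1.25e-05, adjusted p = 0.22 with an estimated correlation). These lists were taken from the data of the other experiment.

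At day 0 edgeR called 212 of 15494 genes, 96 higher and 116 lower, and 901 (390 higher, 511 lower) with the donor as a block. The count was 95 or 139 without KLF2 replicates 2 or 3 and 114 without mNG replicate 1. S1PR5 was not called without KLF2 replicates 2, 4 or 5 or mNG replicate 2 (adjusted p up to 0.0613) or when only the 10 compared libraries were fitted (adjusted p = 0.178).

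**Figure D5:**
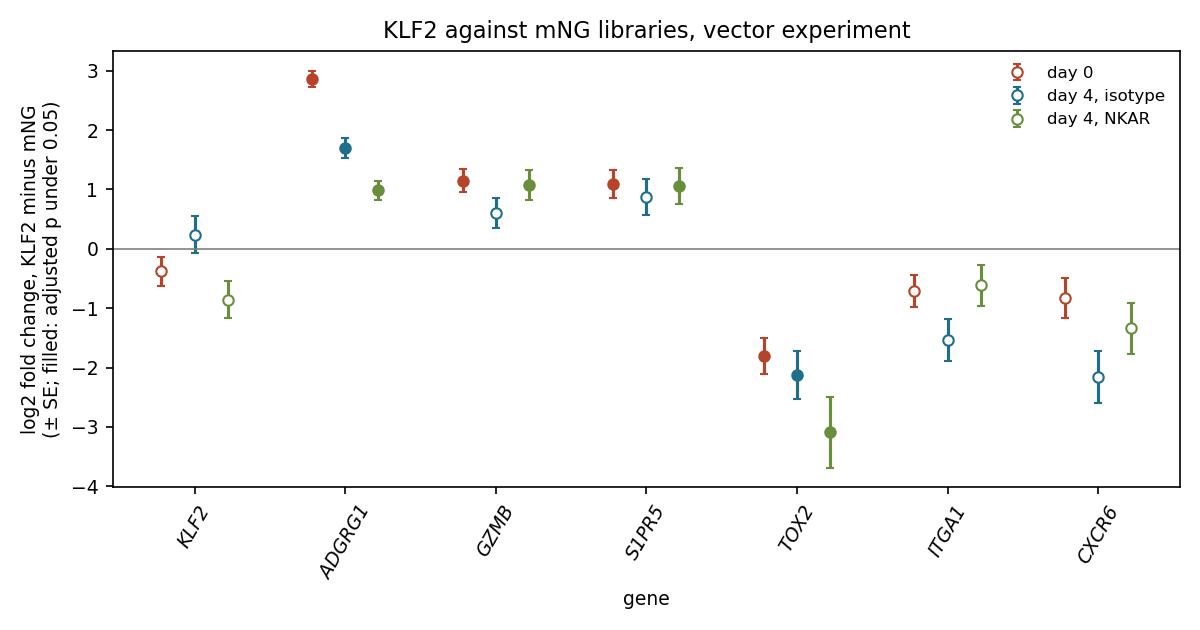
Log2 fold change, KLF2 minus mNG libraries, of 7 genes at day 0 and after 4 days on isotype or NKAR plates; bars are SE and filled points have an adjusted p under 0.05. ADGRG1 lies at 2.87 at day 0 and 1.70 on isotype plates, and KLF2 itself at −0.38, 0.24 and −0.86.

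After 4 days on isotype plates ADGRG1 (338.6 ± 16.6 in 3 KLF2 libraries against 104.1 ± 9.33 CPM in 3 mNG libraries, 1.70, adjusted p = 1.94e-05) was higher in KLF2-labelled libraries in 3 of 3 donors. C1orf162 (18.3 ± 5.12 against 2.03 ± 0.396 CPM, 3.18, adjusted p = 0.000881) and ERBB2 (45.4 ± 6.35 against 13.2 ± 0.882 CPM, adjusted p = 0.0409) were higher in 3 of 3. TOX2 (−2.12, adjusted p = 0.0481) and the phosphatase CTDSPL (−2.25, adjusted p = 0.00375) were lower in 3 of 3. Residency genes did not pass the test, with CXCR6 at −2.16 (adjusted p = 0.0682, lower in 3 of 3). ITGA1 stood at −1.53 (adjusted p = 0.119, and 0.003 with the block, 3 of 3). The CD56dim maturity list was called higher (1 of 12, 6 adjusted over the list alone; adjusted p = 1.55e-08, adjusted p = 0.0738 with an estimated correlation). The egress list was called higher (no member called, 4 of 13 adjusted over the list alone; adjusted p = 9.17e-07, adjusted p = 0.0993 with an estimated correlation). The tissue residency list was called lower (no member called, 3 adjusted over the list alone; adjusted p = 0.00573, adjusted p = 0.0718 with an estimated correlation).

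On isotype plates edgeR called 14 genes, 7 higher and 7 lower, and 270 (125 higher, 145 lower) with the donor as a block. Without KLF2 replicates 1, 2 or 3 the count was 4, 2 or 6, and without mNG replicates 1, 2 or 3 it was 4, 5 or 5. ADGRG1 and C1orf162 kept their calls in each case. ERBB2 and TOX2 lost theirs in each (adjusted p up to 0.199 and 0.281). CTDSPL lost its call without KLF2 replicate 2 (adjusted p = 0.0657). TOX2 was not called with RLE scaling (adjusted p = 0.0525). CXCR6 was called with DESeq2 (adjusted p = 0.000464) and when only the 6 compared libraries were fitted (adjusted p = 0.0309), and ITGA1 with DESeq2 (adjusted p = 0.00837).

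After 4 days on NKAR plates, TNFRSF18, which encodes the costimulatory receptor GITR (47.3 ± 8.03 against 13.0 ± 2.05 CPM, 1.87, adjusted p = 0.00552), was higher in KLF2-labelled libraries in 3 of 3 donors. The potassium channel KCNN4 (73.0 ± 12.2 against 17.98 ± 5.62 CPM, 2.02, adjusted p = 0.00885), FEZ1 (adjusted p = 0.00514, 55.8 ± 16.4 against 18.7 ± 3.6 CPM) and NUDT14 (1.55, adjusted p = 0.00885) were higher in 3 of 3. The cell cycle inhibitor CDKN1A, a p53 target, rose (37.4 ± 8.36 against 12.6 ± 1.16 CPM, 1.57, adjusted p = 0.00756, 3 of 3). So did GZMB (1100 ± 282 against 521.1 ± 123 CPM, 1.08, adjusted p = 0.021, 3 of 3) and S1PR5 (123.5 ± 12.4 against 59.2 ± 0.599 CPM, 1.06, adjusted p = 0.0475, 3 of 3). TOX2 fell (−3.09, adjusted p = 0.00932, lower in 3 of 3). COL6A3, a collagen of connective tissue, was lower (adjusted p = 0.0336), with most of its counts in 1 of 3 mNG libraries (5.75 ± 8.88 against 0.106 ± 0.0929 CPM). In 1 of these 3 mNG libraries 15906 genes had at least 10 counts, against 13238 to 14213 in the other 21 vector libraries. The p53 target list rose (5 of 15; adjusted p = 0.00153, adjusted p = 0.154 with an estimated correlation). So did oxidative phosphorylation (3 of 18, 10 adjusted over the list alone; adjusted p = 0.000231, adjusted p = 0.309 with an estimated correlation). The mitochondrial share was 10.6% ± 1.71 in these KLF2 and 7.20% ± 0.546 in these mNG libraries. Cell cycle genes fell (4 of 23, 10 adjusted over the list alone; adjusted p = 1.45e-05, adjusted p = 0.309 with an estimated correlation). Log2 fold changes in this comparison followed exon length across genes (Spearman rho −0.287).

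On NKAR plates edgeR called 849 genes, 414 higher and 435 lower, and 4056 (1930 higher, 2126 lower) with the donor as a block. The count was 463, 97 or 119 without KLF2 replicates 1, 2 or 3 and 278 or 147 without mNG replicates 1 or 2. S1PR5 lost its call without each of the 6 libraries (KLF2 or mNG replicates 1, 2 or 3, adjusted p up to 0.16), with no filter (adjusted p = 0.0781) and with the length-trend offset (adjusted p = 0.0555). GZMB lost it without KLF2 replicates 1 or 3 or mNG replicate 2 (adjusted p up to 0.106). COL6A3 lost it without KLF2 replicates 1, 2 or 3 or mNG replicate 1 (adjusted p up to 0.308) or with no filter (adjusted p = 0.111).

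Within each vector, NKAR plates were compared with isotype plates. In mNG cells TNFRSF18 (13.0 ± 2.05 against 1.91 ± 0.95 CPM, adjusted p = 0.000421) and ENPP3, an ectonucleotidase, rose in 3 of 3 donors (ENPP3 25.4 ± 1.39 against 2.87 ± 1.21 CPM, 3.15, adjusted p = 0.00309). The death promoter BCL2L11 (97.3 ± 7.09 against 19.4 ± 3.51 CPM, 2.33, adjusted p = 0.00309) and TNFRSF9 (1.89, adjusted p = 0.00424) rose in 3 of 3 as well. TOX2 (adjusted p = 0.000975, 1.34 ± 0.576 against 12.2 ± 2.03 CPM), the metalloprotease MMP25 (−1.33, adjusted p = 0.000783) and the secretory GTPase RAB3D (adjusted p = 0.00274, 8.69 ± 0.392 against 21.04 ± 0.712 CPM) fell in 3 of 3. GZMB stood at 521.1 ± 123 against 1045 ± 305 CPM (adjusted p = 0.0869, and 0.00284 with the donor as a block) and KLF2 at −0.36 (adjusted p = 0.619), each lower in 3 of 3. Costimulatory genes rose (2 of 15, 3 higher and 2 lower adjusted over the list alone; adjusted p = 0.00197, and adjusted p = 0.0215 with an estimated correlation). Cell cycle genes rose (3 of 23, 12 adjusted over the list alone; adjusted p = 2.17e-12, adjusted p = 0.0742 with an estimated correlation). The sterol list was called higher (no member called, 10 of 18 adjusted over the list alone; adjusted p = 3.31e-07, adjusted p = 0.0742 with an estimated correlation). Log2 fold changes followed exon length here as well (rho 0.21). Of 179 genes higher with NKAR in blood 11 rose (31 higher and 1 lower adjusted over the list alone; adjusted p = 5.15e-09, and adjusted p = 0.0215 with an estimated correlation). Of 198 lower genes 4 fell (39 lower and 1 higher adjusted over the list alone; adjusted p = 3.32e-28, adjusted p = 0.059 with an estimated correlation).

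For mNG cells edgeR called 53 genes, 38 higher and 15 lower, and 1770 (1015 higher, 755 lower) with the donor as a block. The count was 18, 12 or 25 without isotype replicates 1, 2 or 3 and 20 without NKAR replicate 1. TNFRSF9 lost its call without isotype replicate 2 (adjusted p = 0.056). GZMB was called with DESeq2 (adjusted p = 0.0119).

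In cells labelled KLF2 ENPP3 (49.0 ± 9.37 against 2.50 ± 1.28 CPM, 4.29, adjusted p = 8.48e-05) and TNFRSF18 rose on NKAR plates in 3 of 3 donors (TNFRSF18 47.3 ± 8.03 against 3.67 ± 0.622 CPM, 3.69, adjusted p = 4.47e-06). BCL2L11 (2.60, adjusted p = 0.000384) and ITGA1 (50.8 ± 5.22 against 15.7 ± 2.57 CPM, 1.70, adjusted p = 0.0145) rose in 3 of 3 as well. KLF2 (51.5 ± 20.1 against 141.3 ± 30.2 CPM, adjusted p = 0.0198) and RAP1GAP2 (11.0 ± 6.58 against 85.1 ± 24.1 CPM, −2.94, adjusted p = 0.000172) fell in 3 of 3. CXCR1 (−2.21, adjusted p = 0.00331), C1orf162 (−2.30, adjusted p = 0.00225) and SGSM1 (−2.24, adjusted p = 0.00299) fell in 3 of 3 too. Costimulatory genes rose (3 of 15, 5 higher and 1 lower adjusted over the list alone; adjusted p = 2.24e-06, and adjusted p = 0.000656 with an estimated correlation). Inhibitory receptors rose (2 of 14, 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0192, adjusted p = 0.0596 with an estimated correlation). CD56dim maturity genes fell (3 of 12, 4 adjusted over the list alone; adjusted p = 3.16e-05, adjusted p = 0.146 with an estimated correlation). Of 179 genes higher with NKAR in blood 27 rose and 1 fell (57 and 1 adjusted over the list alone; adjusted p = 2.7e-30, and adjusted p = 6.27e-05 with an estimated correlation). Of 198 lower genes 38 fell (117 adjusted over the list alone; adjusted p = 1.8e-59, and adjusted p = 0.00293 with an estimated correlation).

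For KLF2 cells edgeR called 271 genes, 151 higher and 120 lower, and 1080 (566 higher, 514 lower) with the donor as a block. The count was 103, 88 or 157 without isotype replicates 1, 2 or 3 and 107, 127 or 150 without NKAR replicates 1, 2 or 3. KLF2 lost its call without isotype replicates 1 or 2 or NKAR replicate 3 (adjusted p up to 0.118) or when only the 6 compared libraries were fitted (adjusted p = 0.0539). ITGA1 lost it without isotype replicates 1, 2 or 3 or NKAR replicate 1 (adjusted p up to 0.079).

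Whether the NKAR effect differed between KLF2 and mNG cells was tested as an interaction. It gave no called gene with edgeR, 25 with DESeq2, 94 (30 higher, 64 lower) with the donor as a block in edgeR, none with the donor as a random effect and 831 at an unadjusted p under 0.05, and KLF2 stood at −1.10 (adjusted p = 0.81). The cell cycle list had a lower NKAR effect in KLF2 cells (no member called over all genes, 10 of 23 adjusted over the list alone; adjusted p = 7.25e-19, and adjusted p = 0.048 with an estimated correlation). The sterol list was called lower (adjusted p = 2.55e-05, adjusted p = 0.241 with an estimated correlation) and oxidative phosphorylation higher (adjusted p = 0.000549, adjusted p = 0.331 with an estimated correlation), each with no member called. Interaction values followed exon length too (rho −0.237).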

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

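The tests on lists of other cell types, with a length offset, of exchanged labels, of too few counts and of the vector insert were chosen only after the result was seen; the others were planned.

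Of 144 checks for a library far from the rest of its group, 10 were positive, where 7.2 would be by chance at 1 in 20. The ratio of the gap to the range was 0.606 for S1PR1 in day 4 NKAR libraries (log2 CPM 2.69 to 4.69, median 3.36; 1 of 7 libraries high). It was 0.61 for S1PR5 in that group (5.82 to 8.26, median 6.26; 1 of 7 high), 0.699 for TCF7 (8.51 to 9.40, median 9.20; 1 of 7 low) and 0.587 for total counts (20.8 to 24.6 M, median 24; 1 of 7 low). In day 4 isotype libraries it was 0.751 for S1PR1 (6.16 to 7.12, median 7.07; 1 of 6 low) and 0.636 for total counts (24.3 to 29.7 M, median 25.8; 1 of 6 high). In day 10 NKAR libraries with continuous IL-15 it was 0.743 for TBX21 (7.14 to 7.79, median 7.29; 1 of 5 high) and 0.734 for the mitochondrial share (5.31% to 6.59%, median 6.47%; 1 of 5 low). It was 0.69 for IFNG in day 10 isotype libraries with continuous IL-15 (−2.47 to 1.85, median 0.595; 1 of 7 low) and 0.719 for KLF2 in day 0 KLF2 libraries (6.32 to 7.16, median 6.95; 1 of 5 low).

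The NKAR effect differed between day 10 with continuous IL-15 and day 4 for 1388 genes by a test of the difference, among them ITGA1 (−1.95, adjusted p = 0.00531), IFNG (−3.39, adjusted p = 0.00632) and TCF7 (−1.30, adjusted p = 0.00966). The count was 879 without replicate 14 of the day 10 NKAR group with continuous IL-15.

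The first pattern is that transcripts of granulocytes, mast cells and red cells were higher in day 10 NKAR than isotype libraries. Medians of basophil and mast and of T cell genes differed by at least 3.372 log2 units (4.83 against 0.201 with gapped IL-15, bootstrap SE 1.15). A lower share of NK cells alone stays open, as NK cultures express some T cell genes (BCL11B) too. A single library is argued against by the mean log2 CPM of the members, by which 9 of 10 day 10 NKAR libraries lay above the highest isotype library of their regime, whereas the summed CPM put 4 of 10 there and is dominated by KIT, which NK cells express. Cells of another type in the cultures may contribute, since 11 of 15 members of the further lists were called higher in both regimes, and 6 of the 8 of them that are in no fixed list and not among the largest changes; apart from KIT (399.3 ± 171 CPM with continuous IL-15) the most abundant were EPX and RNASE2 (both eosinophil genes too) and GATA1 at 6.66, 4.32 and 3.96 CPM. The labels state no sort or gate that would remove such cells, and a change of the NK cells themselves stays open as untested.

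The second pattern is that KLF2 counts were not higher in libraries labelled KLF2. Too few counts to see a doubling is argued against, as the largest upper 95% limit of the KLF2 fold change over the 3 comparisons was 1.86. Vector labels exchanged as a whole could give an upper limit below 0 in all of the 3 comparisons, which 1 did, and this stays open, though 24 of 198 genes lower with NKAR in blood were higher in day 0 KLF2 libraries and none lower; on NKAR plates 22 of 179 genes higher with NKAR in blood were higher and 2 lower. Insert reads that were not assigned to the KLF2 gene may be missing, and with 0 entries in the vector table that are not Ensembl genes this stays open too. A biological explanation, in which the cells lower their own KLF2, was not tested.

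The third pattern is that log2 fold changes followed gene length in the comparison of KLF2 with mNG on NKAR plates (rank correlation across genes −0.287), as they did in the vector interaction (−0.237) and for NKAR in mNG cells (0.21). Length-dependent counting as the source of all calls is argued against, since 74.21% of the 4056 blocked calls (3010 genes) were still called in the same direction with a length offset, while part of them could still come from it. A single library is argued against, as the correlation closest to 0 with 1 library left out was −0.255. A biological source, such as groups of short genes that move together, was not tested, though 8 of 19 ribosomal protein genes rose in this comparison (19 adjusted over the list alone; adjusted p = 0.0549 with an estimated correlation).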

How the results depend on the processing

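The alternatives with an offset for gene length and the fit without 4 libraries were chosen only after the results were seen; the others were planned. No count, fixed list or named gene reversed, but the direction of the further red cell list turned without the 4 libraries chosen by it. The 14 counts of genes stayed within 1.5 times with RLE scaling, with the strict filter and with the length-trend offset. Over all alternatives 230 counts of genes were within that range and 91 were not, 31 of those with 1 library left out. For lists in a comparison 2548 results stayed as they were (called or not), 89 gained a call and 153 lost one, 114 of the latter with an estimated correlation. For named genes 3298 stayed so, 32 gained one and 70 lost one. The donor block changed no call of a named gene other than those given. Why values moved was not tested, except that some fits hold fewer genes or libraries by construction.

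With the donor as a block the count was 2318 for NKAR at day 10 with gapped IL-15, 2657 for the gap in isotype, 400 for the gap in NKAR, 2604 for the day interaction, 901 for KLF2 at day 0, 270 on isotype plates, 4056 on NKAR plates, 1770 for NKAR in mNG cells, 1080 in KLF2 cells and 94 for the vector interaction. With the length-trend offset and the block it was 2227 and 2439 for NKAR at day 10 with continuous and gapped IL-15, 2878 and 430 for the gap in isotype and NKAR, 2751 for the day interaction, 878, 297 and 3575 for KLF2 at day 0, on isotype and on NKAR plates, 1624 and 1155 for NKAR in mNG and KLF2 cells and 65 for the vector interaction. With the donor as a random effect it was 2122 for NKAR at day 10 with gapped IL-15, 2569 and 264 for the gap, 2405 for the day interaction, 835, 107 and 3383 for KLF2, and 570 and 778 for NKAR in mNG and KLF2 cells. Complete pairs with the block gave 144 for the gap in NKAR.

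With an absolute log2 fold change of at least 1 the count was 2621, 786 and 815 for NKAR at day 4 and at day 10 with continuous and gapped IL-15, 407 for the gap in isotype, 555 for the day interaction, 1722 for day 10 against day 4, 105 and 304 for KLF2 at day 0 and on NKAR plates and 159 for NKAR in KLF2 cells, as fewer genes can pass. With no filter it was 910 for the gap in isotype, 780 for the day interaction, 444 for KLF2 on NKAR plates and 167 for NKAR in KLF2 cells, with 34011 and 32706 genes tested. DESeq2 gave 7 for the gap in NKAR, 467, 74 and 1663 for KLF2, 266 and 537 for NKAR in mNG and KLF2 cells and 25 for the vector interaction. With only the libraries compared it was 775 for the gap in isotype, 59, 42 and 1311 for KLF2, and 124 and 474 for NKAR in mNG and KLF2 cells. Without the 4 day 10 NKAR libraries highest in basophil, mast and red cell transcripts it was 725 and 781 for NKAR at day 10 and 760 for the day interaction.

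With 1 library left out in turn the count ranged from 6249 to 7311 for NKAR at day 4, from 1098 to 1432 and from 1067 to 1319 at day 10 with continuous and gapped IL-15, and from 4038 to 4926 for day 10 against day 4. It ranged from 560 to 1716 for the gap in isotype, where the libraries that moved it beyond 1.5 times were continuous replicates 10 (898), 13 (768) and 14 (912) and gapped replicates 1 (764) and 3 (560). It was 0 to 123 for the gap in NKAR (123 without continuous replicate 1), 0 for the interaction of gap and NKAR, and 879 to 1941 for the day interaction (879 without replicate 14 of the day 10 NKAR group with continuous IL-15). For KLF2 it was 95 to 202 at day 0 (95 and 139 without KLF2 replicates 2 and 3, 114 without mNG replicate 1), 2 to 6 on isotype plates (4, 2 and 6 without KLF2 replicates 1, 2 and 3, 4, 5 and 5 without mNG replicates 1, 2 and 3) and 97 to 568 on NKAR plates (463, 97 and 119 without KLF2 replicates 1, 2 and 3, 278 and 147 without mNG replicates 1 and 2). For NKAR it was 12 to 61 in mNG cells (18, 12 and 25 without isotype replicates 1, 2 and 3, 20 without NKAR replicate 1) and 88 to 157 in KLF2 cells (103, 88 and 157 without isotype replicates 1, 2 and 3, 107, 127 and 150 without NKAR replicates 1, 2 and 3). It was 0 for the vector interaction.

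For lists the value is the number of comparisons in which a list was called. With an estimated correlation it was 1 for tissue residency (4 with the preset one), 2 for egress (7), 1 for CD56dim maturity (10), 1 for cytotoxic effectors (6), 0 for cytokines (3), 1 for inhibitory receptors (3), 0 for activating receptors (4), 0 for activation-induced transcription factors (5), 2 for costimulatory genes (6), 2 for chemokine receptors (4), 0 for the TGF-beta response (3), 1 for the cell cycle (9), 0 for glycolysis (5), 0 for sterol synthesis (8), 0 for oxidative phosphorylation (10), 0 for the interferon response (3), 0 for heat shock (7), 0 for p53 targets (8), 0 for T cell (1), 0 for B cell (2), 1 for monocyte and dendritic (3), 0 for platelet and red cell (2), 0 for K562 (1), 3 for the KLF2 cross lists in blood (10) and 5 for the blood cross lists in the vector experiment (10). With the block it was 1 for the IL-15 response, 6 for the interferon response, 1 for ER stress, 2 for T cell and 1 for innate lymphoid genes. With no filter it was 2 for NK lineage, 1 for the IL-15 response, 6 for the TGF-beta response, 7 for the interferon response, 1 for ER stress, 2 for T cell, 4 for B cell, 3 for K562 and 1 for innate lymphoid genes. With only the libraries compared it was 2 for NK lineage, 1 for the IL-15 response, 3 for T cell, 1 for platelet and red cell and 0 for K562. With the length-trend offset it was 0 for K562 and 1 for innate lymphoid genes, and with that offset and the block 8 for activating receptors, 1 for the IL-15 response, 1 for ER stress, 2 for T cell and 1 for innate lymphoid genes.

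In simulated data, where group size, depth and dispersion differ at once, edgeR recovered 31.0% of genes changed 2-fold for KLF2 on NKAR plates (3 libraries per group), against 58.1% for NKAR at day 4. No donor effect was simulated.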

Other observations

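Basophil, mast, red cell and ribosomal lists were chosen after the data were seen and adjusted only among themselves, those from the largest changes included. The splits were planned.

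Ribosomal protein genes, which encode parts of the machinery of translation, were higher with NKAR in blood NK cells at day 4. There 19 of 19 rose (adjusted p = 5.48e-15, adjusted p = 0.16 with an estimated correlation). The NKAR effect on them was lower at day 10 with continuous IL-15 than at day 4 (11 of 19, 18 adjusted over the list alone; adjusted p = 0.155 with an estimated correlation). With NKAR the list was called lower in mNG cells (no member called, 9 of 19 lower with the donor as a block; adjusted p = 3.34e-09, adjusted p = 0.196 with an estimated correlation). It was called higher in KLF2 cells (no member called; adjusted p = 0.0141, adjusted p = 0.701 with an estimated correlation). At day 10, 8 of 10 genes of a further basophil and mast cell list rose with continuous IL-15 (9 adjusted over the list alone; adjusted p = 0.045 with an estimated correlation) and 8 of 10 with gapped IL-15 (adjusted p = 0.0227 with an estimated correlation). Of 5 genes of a further red cell list 4 rose under each regime (5 adjusted over the list alone; adjusted p = 0.24 and 0.232 with an estimated correlation). Of these 15 genes 5 are also in a fixed list and 2 among the largest changes. Of 5 basophil and mast cell genes first noticed among the largest changes, 4 rose with continuous and 5 with gapped IL-15, and both red cell genes noticed so rose under each regime. At day 4, 1 gene of the further basophil and mast cell list was higher and 1 lower of 10, and 2 of 5 red cell genes were higher, with no list called. From day 4 to day 10 in isotype libraries 3 of the 5 first noticed fell (adjusted p = 0.00744, adjusted p = 0.347 with an estimated correlation). FCER1A averaged 1.96 and 0.178 CPM there, and 1.68 and 2.09 CPM with NKAR, so part of the day 10 difference lay in the isotype libraries. Without the 4 NKAR libraries highest in these transcripts, a choice that itself lowers them, no gene of 9 in the further basophil and mast cell list was called with continuous IL-15 and 5 of 9 with gapped IL-15. Of the 5 first noticed 3 were still called higher under each regime, but none of the 3 measured genes of the further red cell list, whose direction turned.

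Other splits of the same libraries were compared with the real one by the number of genes called. Most of the splits drawn in blood part fewer donor pairs than the real one. In 1 of 100 splits, the real one, the real count was reached for NKAR at day 4 (7024, highest other 3107) and at day 10 with continuous (1410, highest other 637) and gapped IL-15 (1414, highest other 480). The same held for the day interaction (1388, highest other 1090) and day 10 against day 4 (4782, highest other 1368). For the gap in isotype 2 of 100 reached it (1384, highest other 1604). This does not exclude chance, as few others part as many pairs, and none for the day interaction. The split with 1604 calls points to a structure of the libraries. Chance cannot be excluded for KLF2 at day 0 (5 of 100; real 212, highest other 3884). There a split with many times the real count points to a structure of the libraries, and the 14 other splits that part all 5 donor pairs gave 0 calls. For the gap in NKAR (real 0, highest other 52), the interaction of gap and NKAR (real 0, highest other 609) and the vector interaction (real 0, highest other 185) the count of splits decides nothing, since with 0 real calls all 100 of 100 reach it. Of the other splits that part as many pairs as the real one, those for NKAR at day 4 and at day 10 with gapped IL-15, for the gap in isotype and for day 10 against day 4 gave 0 calls at most, and those for NKAR at day 10 with continuous IL-15 at most 94. There were 5 such splits for day 10 against day 4 and 2 in each of the others, too few to exclude chance by themselves. The 10 splits of 3 against 3 libraries are too few (1 of 10, highest other 0 in each). This holds for KLF2 on isotype plates (real 14) and NKAR plates (real 849), and for NKAR in mNG cells (real 53) and KLF2 cells (real 271).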
